A study of Mus musculus with 68 samples.

How the data were processed

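RNA libraries of mouse oocytes and embryos were made by Smart-seq2 from polyadenylated RNA and sequenced on a DNBSEQ-T7 instrument, per the labels. The treatment protocol also mentions an inhibitor, GSK343, and its solvent for 1-cell embryos, but no sample used here is labelled with either.

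The 8 deposited tables give FPKM per gene and library, a read count divided by gene length and library total, per the file headers and the labels. Per the submitters' processing notes, Trim Galore 0.4.2, HISAT2 2.2.1 and HTSeq 0.6.0 were used and the builds mm9 and hg19 are named without a role. The tool that computed FPKM, its annotation, the treatment of multi-mapping reads and whether strand was used are not given in the sources used here. Genes of near-identical families, overlapping genes and antisense partners such as Xist and Tsix are therefore uncertain. FPKM are shares of a library, so a transcript that takes a large share lowers all others, as Rn45s can here.

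Columns were matched to samples through their titles. The epiblast columns carry numbers that differ from those of the titles, so they were matched to their group alone. Of 68 libraries 67 were used, because the E4.25 mHet libraries were identical and were counted as 1. In 3 tables, 25, 27 and 27 gene names had been turned into dates and were dropped. Chromosomes were taken by gene name from an annotation of another build (GRCm38.p6), which gave one to 24468 of 24941 genes (98.1%), and no coordinates are printed. Depth cannot be read from the values. The commonest ratio of low values between libraries covered at most 2.75% of genes, so no step worth 1 read was found and no counting interval can be given.

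Each table was analysed alone, since the tables were normalized separately. Genes at 1 FPKM or more in at least 2 libraries of a table were kept. Values were taken as log2(FPKM + 1), so every log2 change is on that scale and understates the change of low genes. Group means of all genotypes of a table were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), and the 6 epiblast and 6 extraembryonic ectoderm libraries were fitted together. The contrasts were knockout against WT, heterozygous against WT, knockout against heterozygous and, at E6.5, the difference of the mKO effect between the tissues, 24 comparisons in all. The p-values are two-sided and were adjusted by Benjamini and Hochberg over the genes kept, with a threshold of 0.05. The single mHet libraries of the 8-cell stage and E4.25 entered the fits without a test of their own.

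Gene lists, 32 in number, covered chromatin complexes, imprinted genes, markers of stages and of embryonic and maternal cell types, and metabolic, ribosomal, cell cycle and stress genes. X-linked genes by the annotation, without Xist, Tsix and Ezhip, made a further list. Lists with at least 5 genes kept were tested with camera of limma, which compares a list with the other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over their list alone. A per-library X offset and a score difference between lists were tested by exact permutation.

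The comparisons, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Ezhip, then up to 10 genes in each direction with the largest log2 change among those past the threshold with a mean of at least 2 FPKM and groups that do not overlap, without predicted or clone-named models. With fewer than 10 genes past the threshold it took the 5 in each direction with the smallest p, as values. Chance alone separates 33.33% of genes with 2 libraries against 2, 20.0% with 3 against 2, 2.86% with 4 against 4 and 0.794% with 5 against 5. Of a list discussed it took up to 4 members past the threshold or else the 2 with the smallest p, and all 6 core genes imprinted through H3K27me3. The text names a selection of the genes the rule took, and 1 of them is not reported here.

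Alternatives changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, median ratio scaling, the 2 groups alone, the replicate number as a block, and each library left out. Where that left a single library in a group, it was assumed to vary like the other groups. For gene lists every alternative kept the preset correlation. Chosen after seeing the data were a sex term from 4 Y-linked transcripts, the library run read from consecutive library names in the labels, Rn45s removed with the rest rescaled, its share divided out, its level as a term, WT replicate 4 as the only WT library at E4.25, embryos matched between the E6.5 tissues by sex, the X offset and the alternatives for knockout against heterozygous.

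The fit was tested on simulated tables with each table's means and spread. A log2 of 1, 2 and 4 was given to 67, 67 and 66 genes. Written after the first run, this check cannot judge the list test, as real genes vary together. Of genes changed by a log2 of 2, the simulation recovered 17.9% in oocytes, where the difference between 2 sets of libraries counted as spread, 77.6% at the 1-cell, 71.6% at the late 2-cell and 67.2% at the 8-cell stage, 13.4% in the first and 71.6% in the second E3.5 table, 28.4% at E4.25, 61.2% in epiblast and 70.1% in extraembryonic ectoderm. For a log2 of 1 it recovered 0% in oocytes, in the first E3.5 table and at E4.25, and at most 16.4%, at the 1-cell stage, so smaller changes would mostly be missed.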

Results

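Polyadenylated RNA was sequenced by Smart-seq2, a full-length method for small amounts of RNA, in mouse oocytes and embryos with genotype labels for Ezhip. Ezhip is an X-linked gene whose product inhibits PRC2, the complex that methylates histone H3 at lysine 27. The series asked how H3K27me3 passes from the oocyte to the next generation, and set wild type (WT) against knockout oocytes or embryos labelled mKO. The 8 tables of FPKM held 68 libraries. Oocytes labelled FGO had 2 WT, 2 heterozygous (Het) and 3 knockout (KO) libraries. The 1-cell embryos (labelled PN5), the late 2-cell embryos, the first E3.5 table, the E6.5 epiblast and the E6.5 extraembryonic ectoderm had 2 libraries each of WT, mHet and mKO. The 8-cell stage had 2 WT, 3 mKO and 1 mHet library and the second E3.5 table held 5 of each genotype. E4.25 had 4 WT and 4 mKO libraries. The E4.25 mHet libraries held identical values in all 19337 genes and were counted as 1 sample, which left 67. No source stated that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

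The read depth is unknown, because FPKM values keep no totals, and no counting interval or detection limit is given. The number of genes at 1 FPKM or more in a library ran from 7316 to 9801 in oocytes, 4940 to 8404 in the second E3.5 table and 5923 to 8988 at E4.25. Rn45s, the ribosomal RNA precursor, took at most 1.47% of the summed FPKM of an oocyte library but 9.19 to 69.5% in the second E3.5 table and 11.7 to 68.6% at E4.25.

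Ezhip (AU022751 in the tables) followed the labels at the 3 stages at which WT libraries expressed it. In oocytes it was 546 and 297 FPKM in WT, 143 and 84.1 in Het, and 0, 0.175 and 0.117 in KO (log2 change -8.53, SE 0.61, limma adjusted p = 6.36e-13). At the 1-cell stage it was 251 and 368 in WT, 157 and 244 in mHet, and 0.933 and 0.124 in mKO (-7.69, SE 0.35, limma adjusted p = 0.000977; 0.0656 without the filter on low values). Late 2-cell embryos held 15.9 and 15.7 in WT, 5.92 and 9.8 in mHet, and 0 and 0.585 in mKO (-3.74, SE 0.36, limma adjusted p = 0.0433). The late 2-cell call ended without the filter (0.516), with a pseudocount of 0.1 (0.252) and without WT replicate 1 (0.497), WT replicate 2 (0.311), mKO replicate 1 (0.463) or mKO replicate 2 (0.209). Its log2 change ran from -4.07 to -3.41 with a library left out and was -3.74 without the filter and -5.93 with the pseudocount. From the 8-cell stage on, the highest library of any genotype was at 1.5 FPKM, so there Ezhip checks no label. The part of the gene that was deleted is not given in the sources used here.

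**Figure D1:**
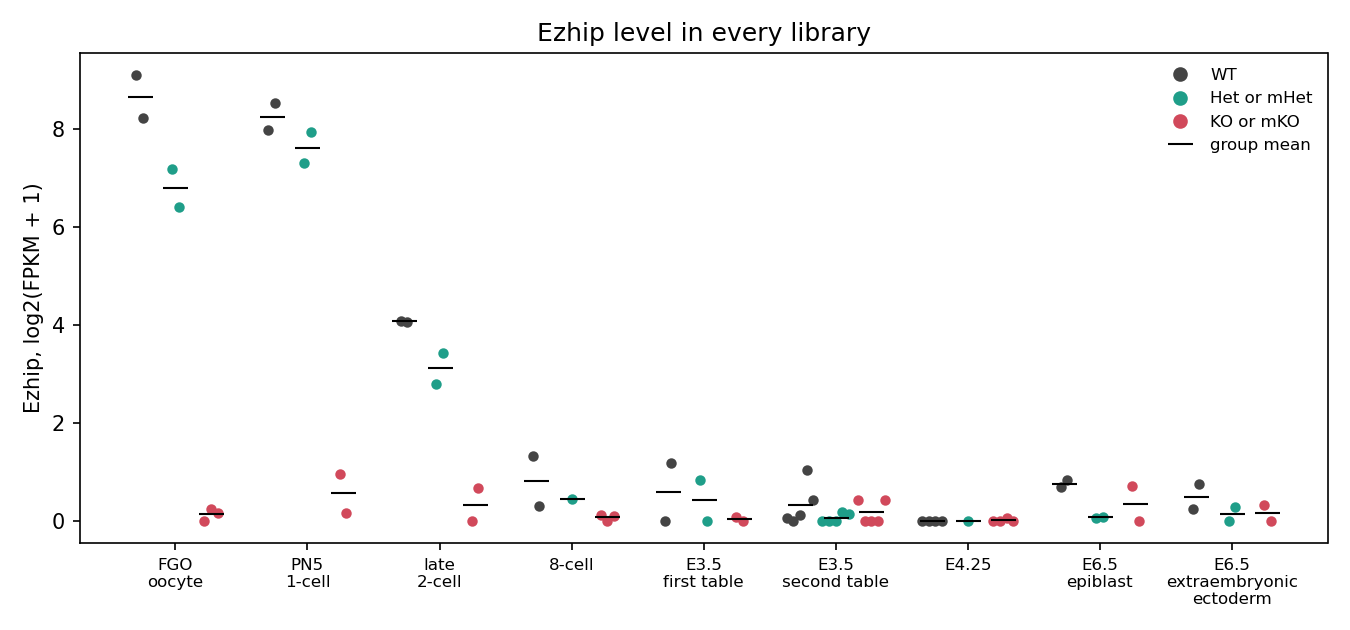
Ezhip as log2(FPKM + 1) in every library, by stage and genotype, with 1 point per library and a bar at each group mean. WT oocytes lie at 297 and 546 FPKM and KO oocytes at or below 0.175 FPKM, and from the 8-cell stage on all genotypes lie near 0.

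In FGO-labelled oocytes, the comparison asked what the loss of Ezhip changed before fertilisation. Ezhip was the only gene to change among 9818 genes kept (limma, 0 higher and 1 lower; 11 genes at an unadjusted p under 0.05). The libraries form 2 sets, WT 1, Het 1, KO 1 and KO 2 with 7316 to 8443 genes at 1 FPKM and WT 2, Het 2 and KO 3 with 9432 to 9801, which are the 2 library runs and which the fit leaves as spread. With the run as a term Ezhip stayed the only gene, with 339 at an unadjusted p under 0.05. The genes with the smallest p-values are given as values that did not pass, each with an adjusted p of 1. Tcl1, an oocyte-stored coactivator of the Akt kinase, stood at 1906 ± 213 against 1463 ± 259 FPKM in KO (SD, n = 3) and WT (n = 2). On the lower side, Cdo1, a cysteine dioxygenase, stood at 87 ± 22 against 157 ± 5.47 FPKM.

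Genes of follicle somatic cells, the cells that surround an oocyte, were lower as a group in KO oocytes relative to the other genes (camera, adjusted p = 0.00038; adjusted p = 0.965 with an estimated correlation). Of its 7 genes, 6 were lower and 0 passed when adjusted over the list alone. Cyp11a1, which starts steroid synthesis from cholesterol, stood at 0.314 ± 0.408 against 2.83 ± 4.0 FPKM. Oocyte-specific genes were higher as a group relative to the other genes (camera, adjusted p = 0.0307; adjusted p = 0.965 with an estimated correlation; 29 of 39 genes higher, 0 adjusted over the list alone). Oog1, a member of an oocyte gene family, stood at 2139.5 ± 957 against 1602 ± 713 FPKM. The follicle call ended without WT replicate 2 (0.489) and without the filter (0.169). The oocyte-specific direction turned without WT replicate 2 (4.52e-13), without KO replicate 1 (0.00581) and with the library run as a term (0.568). That call ended without KO replicate 2 (0.797), with a pseudocount of 0.1 (0.146) and with median ratio scaling (0.831). By genes, 6 genes passed the limma test without WT replicate 1 and 3 without KO replicate 3.

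In 1-cell embryos, the first stage after fertilisation, Ezhip was again the only gene to change among 8604 (limma, 0 higher and 1 lower; 214 genes at an unadjusted p under 0.05, 54 of them higher). The other genes named had an adjusted p of 1. H2afz, the histone variant H2A.Z, stood at 35.9 ± 3.09 against 21.1 ± 0.775 FPKM in mKO and WT (SD, n = 2 each). On the lower side, Pmpcb, a mitochondrial processing peptidase, stood at 6.1 ± 1.25 against 13 ± 1.23 FPKM. Of the 24 gene lists, 0 were called (camera).

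In late 2-cell embryos, the stage at which the mouse genome is activated, the list of 2-cell-stage genes was higher as a group in mKO relative to the other genes (camera, adjusted p = 4.3e-11; adjusted p = 0.99 with an estimated correlation). Of its 34 genes, 27 had a higher mean in mKO, 15 at an unadjusted p under 0.05, and 10 passed when adjusted over the list alone, although 0 passed over all genes. Zfp352, a retrogene of 2-cell embryos, stood at 103 ± 36.6 against 45 ± 8.44 FPKM in mKO and WT (SD, n = 2 each). Gm4340 stood at 63 ± 26.5 against 13.1 ± 4.49 FPKM and Gm5662 at 105 ± 7.64 against 35.9 ± 7.24. Both belong to a family of near-identical copies among which reads may be split. In mHet the same list was lower as a group (camera, adjusted p = 5.71e-07; adjusted p = 0.945 with an estimated correlation; 29 of 34 genes lower). The direct test of mKO against mHet gave a higher list in mKO (camera, adjusted p = 5.76e-20; adjusted p = 0.688 with an estimated correlation). No alternative ended any of these 3 calls.

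**Figure D2:**
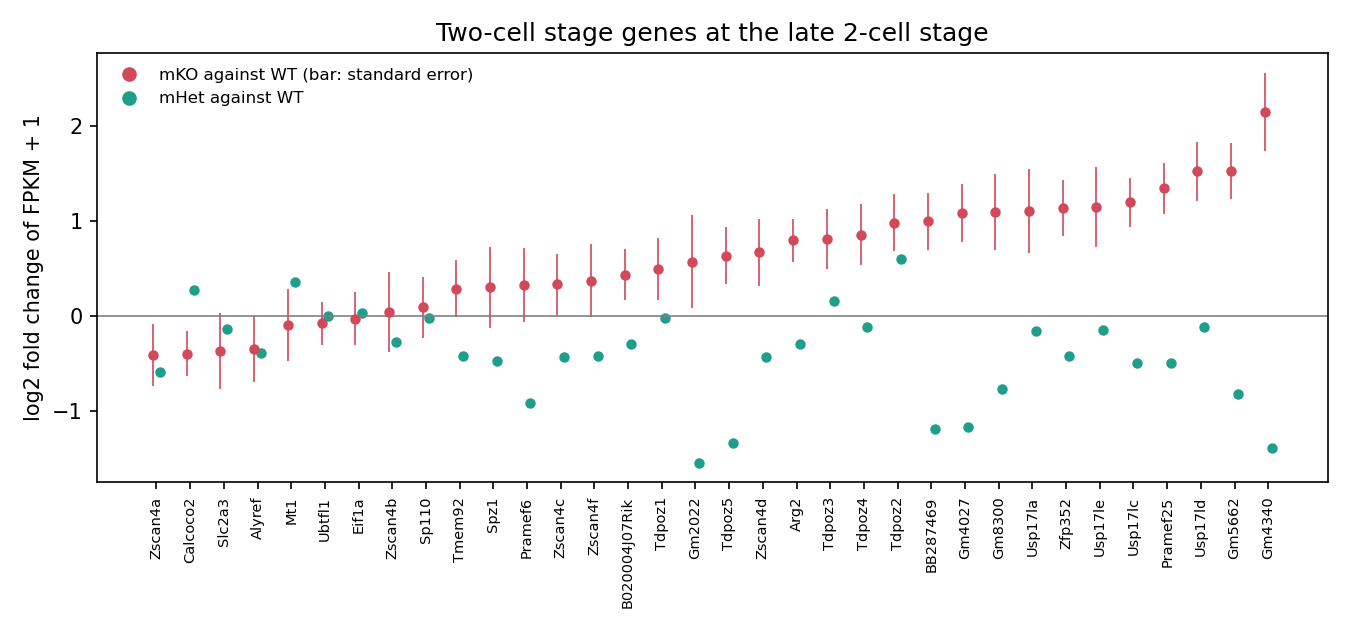
Fold change of each 2-cell-stage gene at the late 2-cell stage, as log2 of FPKM + 1, for mKO against WT (red, with its standard error) and mHet against WT (green), ordered by the mKO value. In mKO 27 of the 34 genes lie above 0 and in mHet 29 lie below it.

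Beyond the list, Ezhip was the only gene to change among 10322 at the late 2-cell stage (limma, 0 higher and 1 lower; 780 genes at an unadjusted p under 0.05, 330 of them higher). Without any 1 of the WT or mKO libraries the count was 0. Mtx2, a metaxin of the outer mitochondrial membrane, stood at 4.3 ± 0.593 against 16.7 ± 0.797 FPKM (adjusted p = 0.252). The list of minor genome activation genes was also higher as a group (camera, adjusted p = 0.0304; adjusted p = 0.99 with an estimated correlation; 1 of 6 adjusted over the list alone), a call that ended without WT replicate 2 (0.125) or mKO replicate 2 (0.29), without the filter (0.138) and with a pseudocount of 0.1 (0.0659).

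In 8-cell embryos Casc4, which encodes a Golgi membrane protein, was the only gene to change among 8319 (limma, 0 higher and 1 lower; 334 genes at an unadjusted p under 0.05, 89 of them higher). Casc4 stood at 0.552 ± 0.0801 against 8.27 ± 1.42 FPKM in mKO (SD, n = 3) and WT (n = 2), a log2 change of -2.57 (SE 0.31, adjusted p = 0.0313). Snx10, a sorting nexin, stood at 1.15 ± 0.259 against 10.6 ± 3.31 FPKM (adjusted p = 0.0578) and Oosp1, secreted by oocytes, at 2.01 ± 0.444 against 9.13 ± 3.66. On the higher side, Serping1, the C1 inhibitor of complement, stood at 5.78 ± 0.539 against 0.531 ± 0.451 FPKM (adjusted p = 0.0911) and Fgf4, a growth factor of the early embryo, at 7.64 ± 1.84 against 1.77 ± 1.22. The Casc4 call ended without WT replicate 1 (0 genes, adjusted p = 0.18), WT replicate 2 (0.232), mKO replicate 1 (0.17) or mKO replicate 2 (0.177). Without mKO replicate 3, 3 genes passed, Snx10 among them (0.0458). It also ended with the filter dropped (0.247), a pseudocount of 0.1 (0.076), median ratio scaling (0.0594) and a sex term (0.163). With the library run as a term 4 genes passed, Snx10 (0.0122) and Serping1 (0.0183) among them.

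X-linked genes were lower as a group in mKO at the 8-cell stage relative to the other genes (camera, adjusted p = 8.31e-10; adjusted p = 0.816 with an estimated correlation), with 213 of 268 genes lower and 24 at an unadjusted p under 0.05. Adjusted over the list alone, 0 passed. This call rested on mKO replicate 2, without which the adjusted p was 0.0671. In that library the median X-linked deviation was -0.59 on the log2 scale from the autosomal one, Xist was at 4.45 FPKM and 4 Y-linked transcripts summed to 40.6 FPKM. The other mKO libraries deviated by 0.0103 and 0.0524, below the WT libraries at 0.0925 and 0.182. Totipotency genes of the 8-cell stage and morula were higher as a group (camera, adjusted p = 0.00818; adjusted p = 0.55 with an estimated correlation; 13 of 17 genes higher, 0 adjusted over the list alone). The totipotency call ended without WT replicate 2 (0.108) and without the filter (0.0505). Ribosomal protein genes were higher as a group (camera, adjusted p = 0.00818; adjusted p = 0.912 with an estimated correlation; 0 adjusted over the list alone) with 63 of 69 genes higher. This call ended without WT replicate 2 (0.90) or mKO replicate 1 (0.697) and with the library run as a term (0.0754).

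At E3.5 the first table compared 2 mKO with 2 WT libraries that differed in sex as well as genotype. Both WT and both mHet libraries held Y-linked transcripts, at 45 to 59.7 FPKM in WT, and the mKO libraries at most 0.151 FPKM, with Xist at 36.7 and 97.8 FPKM. Genotype and sex cannot be told apart in this table. Among 9834 genes, 2 rose and 2 fell (limma; 539 at an unadjusted p under 0.05), and the median log2 change of all genes was 0.21. Tsix, the antisense RNA of Xist, was at 79.4 ± 27.5 against 3.63 ± 2.25 FPKM in mKO and WT (SD, n = 2 each; 4.17, SE 0.49, adjusted p = 0.050). Xist itself was at 67.2 ± 43.2 against 2.04 ± 2.42 FPKM (adjusted p = 0.0831; 0.00149 without WT replicate 1, 0.0196 without WT replicate 2, 0.0313 without mKO replicate 2 and 2.22e-05 with the Rn45s level as a term). Without a stated strand the reads of the pair cannot be told apart. Prl3b1, a placental lactogen of trophoblast giant cells, was at 9.34 ± 3.41 against 0.0781 ± 0.11 FPKM (3.23, SE 0.39, adjusted p = 0.050). Eif2s3y, a Y-linked translation factor gene, was at 0.0729 ± 0.00184 against 38.8 ± 9.67 FPKM (-5.19, SE 0.50, adjusted p = 0.0326) and BC051665 at 0.473 ± 0.233 against 24.6 ± 8.62 (-4.09, SE 0.48, adjusted p = 0.050). The other genes given for this table did not pass, among them Ddx3y, also Y-linked, at 0.0399 ± 0.0565 against 8.44 ± 3.35 FPKM (adjusted p = 0.0539). Myl9, a myosin light chain, stood at 1.13 ± 0.667 against 33.8 ± 20 FPKM. Both passed with median ratio scaling (0.00771 and 0.0202), Rn45s removed (0.00676 each) or its level as a term (0.00219 and 0.00981), and Ddx3y with a pseudocount of 0.1 (0.0129). Without the filter no gene passed. Tsix no longer passed with a pseudocount of 0.1 (0.0731), median ratio scaling (0.0559), Rn45s removed (0.051) or the 2 groups alone (0.236), nor Prl3b1 without mKO replicate 2 (0.157), with a pseudocount of 0.1 (0.0662) or the 2 groups alone (0.0644), nor BC051665 with the latter (0.0579). The same held for Eif2s3y and BC051665 without mKO replicate 1 (0.0529 and 0.0529) or mKO replicate 2 (0.157 and 0.26). The count of 4 became 35 without WT replicate 1, whose Rn45s share of 21% was the highest of the table, 52 without WT replicate 2, with Ddx3y (0.00347 and 0.0177) and Myl9 (0.00347 and 0.0309) among both, and 2 without mKO replicate 2, and the split of 2 higher and 2 lower became 1 and 4 with median ratio scaling and 4 and 8 with Rn45s removed.

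Gene groups in the first E3.5 table moved in both directions. Germline and placental genes of X-linked clusters were lower as a group in mKO (camera, adjusted p = 9.41e-08; adjusted p = 0.849 with an estimated correlation), with 7 of 12 genes lower and 1 higher adjusted over the list alone. Xlr4b stood at 2.95 ± 0.0938 against 13.4 ± 5.35 FPKM (0.0364 with the Rn45s level as a term). Genes of extraembryonic ectoderm, the trophoblast lineage next to the epiblast, were lower as a group (camera, adjusted p = 0.000174; adjusted p = 0.917 with an estimated correlation; 0 higher and 0 lower adjusted over the list alone), with the trophoblast factor Eomes at 4.93 ± 2.83 against 16.3 ± 6.94 FPKM. Genes of the p53 and integrated stress responses were higher as a group (camera, adjusted p = 0.000633; adjusted p = 0.917 with an estimated correlation; 0 higher adjusted over the list alone). Ribosomal protein genes were higher as a group (camera, adjusted p = 1.24e-07; adjusted p = 0.917 with an estimated correlation; 0 adjusted over the list alone), all 69 of them with a higher mean in mKO.

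The second E3.5 table, with 5 libraries of each genotype, put the clearest decreases on the X chromosome. Of 9273 genes, 0 rose and 5 fell in mKO (limma; 534 at an unadjusted p under 0.05, 61 of them higher), and 4 of the 5 lie on X. Xlr3a, of an X-linked multicopy family whose reads may be shared, was at 0.29 ± 0.107 against 3.9 ± 1.28 FPKM in mKO and WT (SD, n = 5 each; -1.89, SE 0.26, adjusted p = 0.00724). Msn, the X-linked membrane linker moesin, was at 1.47 ± 0.602 against 9.68 ± 3.03 FPKM (-2.10, SE 0.30, adjusted p = 0.00724). Fam122b was at 1.2 ± 0.415 against 7.42 ± 3.31 FPKM (-1.89, SE 0.28, adjusted p = 0.00852) and Firre, an X-linked long non-coding RNA, at 0.32 ± 0.173 against 2.48 ± 1.19 (-1.34, SE 0.22, adjusted p = 0.0259). Stag3, a cohesin subunit of meiosis on chromosome 5, was at 0.847 ± 0.411 against 3.89 ± 1.0 FPKM (-1.41, SE 0.24, adjusted p = 0.0303). On the higher side, none passed. Plod2, a collagen lysyl hydroxylase, stood at 8.58 ± 3.8 against 2.19 ± 0.555 FPKM (adjusted p = 0.122) and passed without mKO replicate 4 (0.025), with median ratio scaling (0.0105), Rn45s removed (0.0405) or its level as a term (0.0029). No alternative ended the Xlr3a and Msn calls. Rn45s removal ended those of Fam122b (0.137), Firre (0.233) and Stag3 (0.529), median ratio scaling those of Firre (0.0577) and Stag3 (0.271), as did dropping the filter (0.0867 and 0.0972) and a sex term (0.0527 and 0.0616), and the 2 groups alone that of Firre (0.0653). Firre lost its call without WT replicate 5 (0.052), 6 (0.0718) or 7 (0.0907) or mKO replicate 5 (0.119) or 6 (0.112). Stag3 lost it without WT replicate 4 (0.0994), 5 (0.10), 6 (0.122) or 7 (0.0584) or mKO replicate 5 (0.155) or 6 (0.141). The count fell to 3 without any of WT replicates 5 to 7 or mKO replicates 5 and 6 and rose to 12 without mKO replicate 7, with 2 higher and 3 lower after Rn45s removal and 9 and 13 with the Rn45s level as a term.

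As a group, the X-linked genes were lower in mKO in the second E3.5 table (camera, adjusted p = 9.49e-06; adjusted p = 0.957 with an estimated correlation), with 212 of 288 lower and, adjusted over the list alone, 0 higher and 26 lower. Germline and placental genes of X-linked clusters were lower too (camera, adjusted p = 3.87e-06; adjusted p = 0.942 with an estimated correlation; 6 of 13 lower adjusted over the list alone; adjusted p = 0.46 without the filter). Plac1, an X-linked placental gene, stood at 0.0529 ± 0.0802 against 4.71 ± 1.7 FPKM, Xlr3b at 0.348 ± 0.421 against 4.32 ± 2.33 and Xlr4b at 0.879 ± 0.76 against 5.5 ± 2.44. These 3 genes, chosen after their values were seen, did not pass over all genes. Plac1 did with the 2 groups alone (0.00177), as did Xlr3b (0.0455), which also passed without WT replicate 3 (0.0443). Xlr3b and Xlr4b both passed without mKO replicate 7 (0.0379 and 0.0446), with median ratio scaling (0.0353 and 0.0494) and with the Rn45s level as a term (0.0212 and 0.035). A per-library offset, the median X-linked minus the median autosomal deviation, averaged 0.12 ± 0.10 in WT, -0.058 ± 0.0727 in mHet and -0.0664 ± 0.13 in mKO (SD, n = 5 each). The offset differed by -0.18 between mKO and WT (two-sided exact permutation p = 0.0159, adjusted p = 0.0318 over the 2 stages large enough to test) and by -0.17 between mHet and WT (exact permutation p = 0.0159). At E4.25, the other stage, the difference was 0.0293 (exact permutation p = 0.60). Both E3.5 differences were lost without the filter (-0.00388 and -0.0348).

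**Figure D3:**
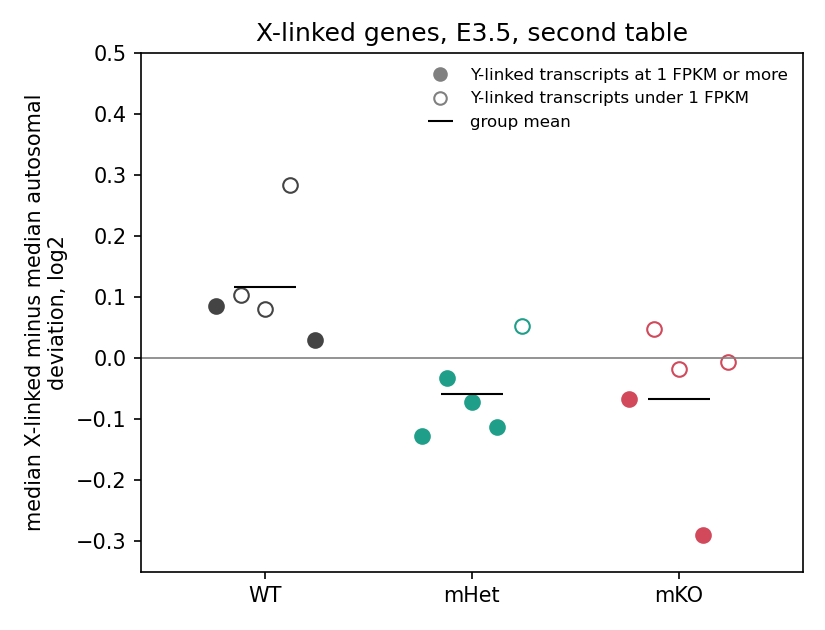
Median X-linked minus median autosomal deviation from the mean of the table, in log2, for each library of the second E3.5 table by genotype, with bars at group means and filled points for libraries with Y-linked transcripts at 1 FPKM or more. Means are 0.12 (WT), -0.058 (mHet), -0.0664 (mKO).

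Trophoblast and stress genes also moved as groups in the second E3.5 table. Genes of the trophectoderm, the outer layer that forms the placenta, were lower in mKO (camera, adjusted p = 1.13e-05; adjusted p = 0.942 with an estimated correlation), with 28 of 32 lower and 1 adjusted over the list alone. Genes of the p53 and integrated stress responses were higher (camera, adjusted p = 0.000116; adjusted p = 0.942 with an estimated correlation; 14 of 18 higher, 0 adjusted over the list alone), with Cdkn1a, a p53 target that halts the cell cycle, at 22.8 ± 16.1 against 9.15 ± 6.5 FPKM. Of the genes called in the second E3.5 table, 4 were tested in the first and all 4 had the same sign there. Msn was at -1.69 and Stag3 at -0.31 on the log2 scale. The tables, deposited separately and with sex differing in the first, shared 0 calls.

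At E4.25 the number of genes that passed was far larger than at any other stage. In mKO, 1370 genes rose and 24 fell among 9550 (limma), of which 75 of the higher were small RNA or microRNA genes, and the median log2 change of all genes was 0.74. Pramel6 and Pramel7, of a Prame-like family expressed in early embryos, were at 183 ± 64.3 against 8.61 ± 13.6 FPKM (5.29, SE 0.88, adjusted p = 0.00365) and 62.5 ± 13.9 against 3.65 ± 5.76 FPKM in mKO and WT (SD, n = 4 each). Dppa3, the maternal factor Stella, was at 67.5 ± 55 against 1.55 ± 1.31 FPKM (4.32, SE 0.73, adjusted p = 0.00365), and Pou5f1, the pluripotency factor Oct4, at 14.5 ± 10.1 against 0.714 ± 0.642 (adjusted p = 0.00499). Further genes that rose were Alpl, an alkaline phosphatase, at 126 ± 75.8 against 7.05 ± 6.89 FPKM, Slc15a2, a peptide transporter, at 52.9 ± 33 against 2.29 ± 3.3, Calcoco2, an autophagy receptor, at 274 ± 119 against 20.5 ± 19.6, and Wtap, of the complex that methylates adenosine in RNA, at 111 ± 32.5 against 7.39 ± 4.01. Among the genes that fell, Ccnd1, cyclin D1, was at 0.41 ± 0.253 against 4.01 ± 2.65 FPKM (-1.66, SE 0.43, adjusted p = 0.0223) and Slc40a1, the iron exporter ferroportin, at 0.186 ± 0.281 against 4.39 ± 4.18. Ccdc39, a gene of motile cilia, was at 0.056 ± 0.0584 against 10.8 ± 17.5 FPKM (adjusted p = 0.0397). The E4.25 libraries also differed in how much of the signal Rn45s took. Its share was 21, 38.6, 68.6 and 60.5% in WT, with 5923 to 7207 genes at 1 FPKM, and 24.2, 11.7, 52.4 and 26.6% in mKO, with 7194 to 8988. Of the WT libraries 3 also stood apart, with a median rank correlation to the other libraries of the table of 0.646, 0.628 and 0.366 (replicates 1 to 3), against 0.80 in WT replicate 4 and 0.795 to 0.825 in mKO. Without these 3, which leaves 1 WT library, 0 genes passed (limma; 1302 at an unadjusted p under 0.05). With median ratio scaling, which moved the median change to 0.11, 30 genes rose and 1 fell, and of the 11 genes named for this stage so far Wtap alone passed (adjusted p = 0.0309). Without the filter on low values Dppa3 (0.0507), Alpl (0.0589), Calcoco2 (0.0508) and the 3 lower genes no longer did. The count became 478 without WT replicate 2, 533 without mKO replicate 1, 421 without mKO replicate 2 and 297 without mKO replicate 4. By library run, 660 genes passed in the first run (2 WT and 2 mKO libraries) and 0 in the second. With Rn45s removed and the rest rescaled 69 genes passed, with its share alone divided out 348, and with its level as a term 1555. Pramel7 (0.0575), Ccnd1 (0.0868) and Ccdc39 (0.189) lost their calls with Rn45s removed. Ccnd1 also lost it without mKO replicate 1 (0.0576), 2 (0.0551) or 4 (0.0884) and in the first run (0.0747), and Slc40a1 without WT replicate 2 (0.0696) or mKO replicate 1 (0.0734) or 4 (0.079). Ccdc39 did so without WT replicate 1 (0.0549) or 2 (0.0504), without any 1 mKO library (0.0615 to 0.0987), with the Rn45s level as a term (0.0834) or its share divided out (0.121), and in the first run (0.0555).

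**Figure D4:**
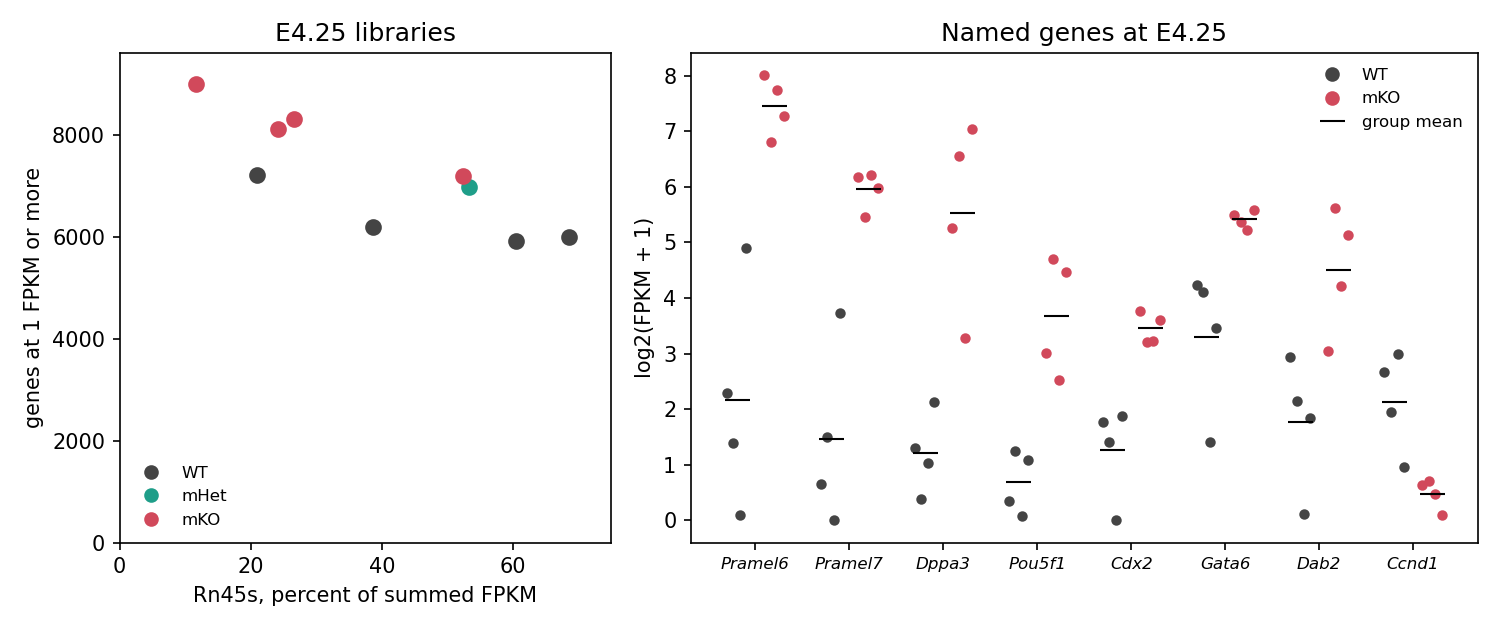
Left, genes at 1 FPKM or more against the percent of summed FPKM taken by Rn45s, 1 point per E4.25 library; right, log2(FPKM + 1) of named genes in each WT and mKO library with bars at group means. The WT libraries hold 5923 to 7207 such genes and the mKO libraries 7194 to 8988.

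Gene groups at E4.25 were tested relative to the shift of all genes. Totipotency genes of the 8-cell stage and morula were higher as a group in mKO (camera, adjusted p = 0.000798; adjusted p = 0.861 with an estimated correlation; median log2 change 2.15), with 11 of 20 genes past the threshold over all genes and 15 adjusted over the list alone. No alternative ended this call. Pluripotency genes of the inner cell mass were higher (camera, adjusted p = 0.0279; adjusted p = 0.861 with an estimated correlation; 8 of 25 called, 9 adjusted over the list alone). This call ended without mKO replicate 2 (0.051) or 3 (0.121), with the Rn45s level as a term (0.059) and in the first run (0.234). Genes of visceral endoderm, a yolk sac lineage, were lower relative to the other genes (camera, adjusted p = 0.000179; adjusted p = 0.861 with an estimated correlation; median -0.45, mean -0.0521), although the 2 members past the threshold rose, namely Gata6, an endoderm transcription factor, at 41.9 ± 4.65 against 11.4 ± 7.33 FPKM and Dab2, an endocytic adaptor of endoderm, at 26.8 ± 18 against 3.19 ± 2.71. Adjusted over the list alone, 1 member was higher and 0 lower. The visceral endoderm call was lost with median ratio scaling (0.0884), with Rn45s removed (0.0704), in the second library run (0.27) and without WT replicates 1 to 3 (0.683). Cdx2, the trophectoderm factor, rose to 10.1 ± 2.16 against 1.69 ± 1.21 FPKM (adjusted p = 0.013; 0.0503 without mKO replicate 4). Dab2 lost its call without mKO replicate 2 (0.065) or 4 (0.0682), and Gata6 without WT replicate 2 (0.0681), 3 (0.0719) or 4 (0.077) or mKO replicate 1 (0.117), 2 (0.114) or 4 (0.133), with a pseudocount of 0.1 (0.064) or with the Rn45s share divided out (0.0695). All 3 calls ended without the filter (0.0561 to 0.112), with median ratio scaling (0.171 to 0.27), with Rn45s removed (0.136 to 0.242) and in the first run (0.0639 to 0.189).

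Of the PRC2 genes, whose list was not called at any stage, Mtf2, an accessory subunit, was at 65.6 ± 19.7 against 10.1 ± 10.8 FPKM at E4.25 (adjusted p = 0.0156) and Eed, a core subunit, at 22.5 ± 10.3 against 5.21 ± 2.7 (adjusted p = 0.0339), both of n = 4. Mtf2 lost its call without WT replicate 2 (0.050) or mKO replicate 4 (0.0634), and Eed without WT replicate 2 (0.0616) or 3 (0.0549) or mKO replicate 1 (0.085), 2 (0.115) or 4 (0.0932), with a pseudocount of 0.1 (0.0512) and in the first run (0.0702). Both ended without the filter (0.0638 and 0.0816), with median ratio scaling (0.181 and 0.217), with Rn45s removed (0.15 and 0.174) and with its share divided out (0.052 and 0.0522). Of the genes imprinted through H3K27me3 of the oocyte, Gab1, a signalling adaptor, stood at 7.74 ± 2.41 against 2.54 ± 1.5 FPKM (adjusted p = 0.055; 0.030 without WT replicate 1, 0.0366 without mKO replicate 3, 0.0367 with a sex term, 0.0351 with the run and 0.0457 with the Rn45s level as a term). Sfmbt2, a polycomb group gene, stood at 6.03 ± 2.94 against 2.28 ± 1.52, Slc38a4, an amino acid transporter, at 16.1 ± 8.7 against 5.87 ± 5.0 (0.0371 with a sex term), Smoc1 at 1.26 ± 0.23 against 0.713 ± 0.898 and Xist at 64.2 ± 67 against 7.85 ± 5.62 (0.0215 with a sex term and 0.041 with the run). Xist followed sex in mKO, at 94.5 and 144 FPKM in the 2 libraries without and 12.4 and 5.74 in the 2 with Y-linked transcripts, which 3 of the 4 WT libraries held. In the second E3.5 table Gab1 stood at 4.77 ± 2.84 against 2.55 ± 1.26 FPKM, Slc38a4 at 5.18 ± 5.48 against 7.44 ± 2.32, Sfmbt2 at 4.26 ± 6.38 against 2.84 ± 1.94, Jade1, another name of Phf17, at 1.73 ± 0.578 against 1.26 ± 0.495 and Xist at 104 ± 57.2 against 97.2 ± 67.8 (n = 5 each). Here mKO replicate 7 alone held Sfmbt2 at 15.6 and Slc38a4 at 14.9 FPKM, against 0.781 to 2.1 and 1.73 to 3.65 in the other mKO libraries and, for Slc38a4, 5.26 to 11.4 in WT. The log2 changes of -0.0323 and -0.74 became -0.60 and -1.16 without it (adjusted p = 0.506 and 0.192). In the first they stood at 12.5 ± 2.8 against 7.31 ± 2.65 for Gab1, 14.7 ± 7.42 against 24.2 ± 12.3 for Slc38a4, 3.5 ± 2.61 against 4.76 ± 0.388 for Sfmbt2, 6.77 ± 4.51 against 6.09 ± 4.34 for Phf17 and 1.32 ± 0.0103 against 0.93 ± 0.20 for Smoc1 (n = 2 each). Without an added term and with all libraries none of these imprinted genes passed at these stages.

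In E6.5 epiblast, the tissue that forms the embryo proper, Casc4 was the only gene to change in mKO among 11028 (limma, 0 higher and 1 lower; 490 at an unadjusted p under 0.05, 301 of them higher). It was at 0.875 ± 0.0648 against 7.42 ± 0.674 FPKM in mKO and WT (SD, n = 2 each; -2.17, SE 0.26, adjusted p = 0.0224). The table numbers its epiblast columns 3 and 4 where the titles number them 1 and 2, so these libraries are given by column. The Casc4 call ended, and the count fell to 0, without WT column 3 (0.539), WT column 4 (0.139), mKO column 3 (0.222) or mKO column 4 (0.0989), as well as with a pseudocount of 0.1 (0.457), median ratio scaling (0.157), the 2 groups alone (0.351) and a sex term (0.057). Tagln3 stood at 0.572 ± 0.222 against 3.6 ± 0.454 FPKM (adjusted p = 0.193; 0.0426 without the filter).

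Pluripotency genes of the inner cell mass were higher as a group in mKO epiblast (camera, adjusted p = 4.35e-05; adjusted p = 0.194 with an estimated correlation), with 5 of 25 higher adjusted over the list alone. Gdf3, a growth factor of pluripotent cells, stood at 14.2 ± 7.8 against 4.55 ± 1.63 FPKM and Fgf4 at 17 ± 0.232 against 5.83 ± 4.35. Genes of the p53 and integrated stress responses were higher as a group (camera, adjusted p = 0.000229; adjusted p = 0.509 with an estimated correlation; 0 of 22 adjusted over the list alone). No alternative ended these calls. Genes of the primitive streak, where mesoderm and endoderm arise, were lower as a group (camera, adjusted p = 0.0425; adjusted p = 0.637 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone), with Fgf8 at 1.46 ± 1.16 against 12.9 ± 6.77 FPKM. The direction turned without WT column 3 (0.306) and the call ended without mKO column 3 (0.422), with a pseudocount of 0.1 (0.076), without the filter (0.0771), with median ratio scaling (0.0724) and with the 2 groups alone (0.174).

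Markers of trophoblast were measured in the epiblast libraries as signs of another tissue. Trophectoderm genes were higher as a group in mKO (camera, adjusted p = 1.11e-05; adjusted p = 0.509 with an estimated correlation; 0 higher adjusted over the list alone), as were those of extraembryonic ectoderm (camera, adjusted p = 0.000809; adjusted p = 0.509 with an estimated correlation; 0), with Elf5 at 9.21 ± 12.9 against 0.0715 ± 0.0595 FPKM and Bmp4, a signal from extraembryonic ectoderm, at 9.95 ± 12.6 against 0.937 ± 0.154, both chosen after their values were seen. Without mKO column 3 both calls ended (0.422 and 0.906). The 6 core genes imprinted through H3K27me3 were higher as a group in mKO epiblast (camera, adjusted p = 0.00345; adjusted p = 0.509 with an estimated correlation; 1 adjusted over the list alone). This call too ended without mKO column 3 (0.422) and without WT column 3 (0.0686). Gab1 stood at 5.93 ± 4.0 against 0.99 ± 0.192 FPKM, Sfmbt2 at 2.13 ± 2.8 against 0.0818 ± 0.0302, Slc38a4 at 21 ± 14.4 against 9.12 ± 0.835, Phf17 at 7.04 ± 3.73 against 4.3 ± 3.65, Smoc1 at 0.943 ± 0.22 against 0.629 ± 0.11 and Xist at 4.9 ± 6.68 against 7.52 ± 10.4 (n = 2 each).

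Extraembryonic ectoderm at E6.5, from which much of the placenta forms, had 0 changed genes in mKO among 11028 (limma; 854 at an unadjusted p under 0.05, 267 of them higher; smallest adjusted p = 0.127), with a median log2 change of -0.19. The 6 core genes imprinted through H3K27me3 were higher as a group relative to the other genes (camera, adjusted p = 0.00483; adjusted p = 0.773 with an estimated correlation; 5 of 6 higher, 1 adjusted over the list alone), a call that no alternative ended at the preset correlation. Smoc1, a secreted calcium-binding protein, stood at 5.59 ± 0.778 against 1.49 ± 0.388 FPKM in mKO and WT (SD, n = 2 each; 1.41, SE 0.25, adjusted p = 0.168). Gab1 stood at 46.1 ± 2.77 against 24.5 ± 2.74 FPKM (0.89, SE 0.50, adjusted p = 0.682), Phf17 at 33.4 ± 3.28 against 23.2 ± 9.16, Slc38a4 at 59.8 ± 17.7 against 51.6 ± 0.737, Sfmbt2 at 26.1 ± 4.93 against 27.6 ± 6.69 and Xist at 5.63 ± 7.03 against 3.75 ± 5.0. WT epiblast held Gab1 at 0.99 and Sfmbt2 at 0.0818 FPKM, and markers of epiblast and visceral endoderm moved too, so a changed mix of cell types is not told apart from a change of these genes.

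**Figure D5:**
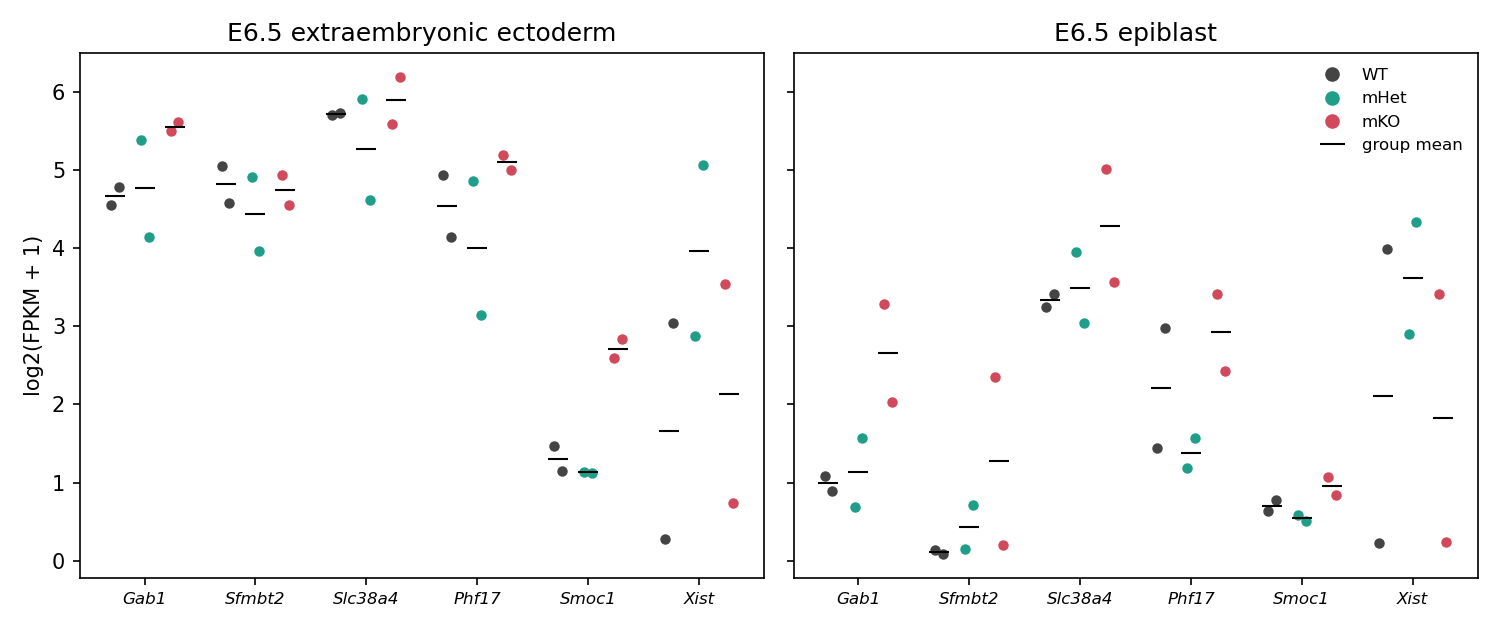
The 6 core genes imprinted through H3K27me3 as log2(FPKM + 1) in each E6.5 library of extraembryonic ectoderm (left) and epiblast (right), 1 point per library and a bar at each group mean. In extraembryonic ectoderm Smoc1 averages 5.59 against 1.49 FPKM and Gab1 46.1 against 24.5 FPKM in mKO and WT.

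The genes of extraembryonic ectoderm with the smallest p-values are given as values that did not pass. Mtfr1, a regulator of mitochondrial fission, stood at 4.07 ± 0.221 against 36.6 ± 1.18 FPKM (adjusted p = 0.128), Sh3bgrl at 1.77 ± 0.255 against 15.5 ± 1.07, Ifitm1 at 1.83 ± 1.96 against 15.1 ± 6.66 (0.028 without mKO replicate 1) and Ccl20, a chemokine, was listed at 0 in both mKO libraries and at 3.87 ± 0.284 FPKM in WT (adjusted p = 0.127; 0.029 with a pseudocount of 0.1). With median ratio scaling 4 genes passed, all lower, among them Mtfr1 (0.0139) and Sh3bgrl (0.0482), and 9 passed without mKO replicate 1 and 1 without WT replicate 2.

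Other cell types moved with the mKO label in extraembryonic ectoderm. Visceral endoderm genes were higher as a group (camera, adjusted p = 1.82e-07; adjusted p = 0.773 with an estimated correlation; 13 of 16 higher, 2 adjusted over the list alone), and the call ended without mKO replicate 2 (0.124). Spink3 and Apoc2, both abundant in visceral endoderm, averaged 11.7 ± 12.9 and 36.6 ± 48.8 FPKM in mKO. WT was at 0 for Spink3 and 0.214 for Apoc2, which passed without mKO replicate 1 (0.000234). Genes of the E6.5 epiblast were lower as a group (camera, adjusted p = 0.00483; adjusted p = 0.773 with an estimated correlation; 20 of 25 lower, 7 adjusted over the list alone), with Tdgf1, the epiblast co-receptor Cripto, at 0.503 ± 0.36 against 24.4 ± 29.3 FPKM (adjusted p = 0.348; 0.0469 without WT replicate 2). The epiblast call ended without WT replicate 1 (0.0821), without mKO replicate 2 (0.138) and with the 2 groups alone (0.0999). Trophectoderm genes were higher as a group (camera, adjusted p = 0.00223; adjusted p = 0.773 with an estimated correlation; 2 adjusted over the list alone) under every alternative. X-linked genes were lower as a group (camera, adjusted p = 0.00643; adjusted p = 0.773 with an estimated correlation; 333 of 423 lower, 10 adjusted over the list alone), but not without mKO replicate 2 (0.567), the mKO library with Y-linked transcripts (44.1 FPKM), or without the filter (0.0646).

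The direct test of whether the mKO effect differed between extraembryonic ectoderm and epiblast, which takes the tissues as independent, called 0 genes (limma; 376 at an unadjusted p under 0.05; smallest adjusted p = 0.76), and 5 genes without extraembryonic mKO replicate 1. Casc4, the first of these, had a difference of 2.14 (SE 0.36). Over the 9 comparisons of knockout with WT, 59 list tests passed with the preset correlation, and 0 lists passed with an estimated correlation in any of the 24 comparisons fitted, where the smallest adjusted p was 0.194. The lists of classically imprinted genes, of PRC2, of DNA methylation enzymes and of other histone methylation enzymes were called in none of the knockout comparisons.

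Heterozygous libraries differed from WT in few genes. In epiblast 2 genes rose and 1 fell in mHet (limma). Id1, an inhibitor of basic helix-loop-helix factors induced by BMP, was at 132 ± 75.3 against 5.88 ± 4.85 FPKM (4.36, adjusted p = 0.0295) and Lefty1, a Nodal inhibitor, at 29.2 ± 6.2 against 2.21 ± 2.34 (3.44, adjusted p = 0.0295; SD, n = 2 each). Casc4 was at 0.986 ± 0.404 against 7.42 ± 0.674 FPKM (-2.10, adjusted p = 0.0295), against the same WT libraries as in mKO. All 3 calls ended without WT column 4 (0.369, 0.349 and 0.349 in that order), mHet column 3 (0.0998, 0.476 and 0.217) or mHet column 4 (0.223, 0.223 and 0.144), and Casc4 also without WT column 3 (0.241). All 3 ended with a pseudocount of 0.1 (0.142 to 0.678), median ratio scaling (0.0934) and the 2 groups alone (0.368 to 0.479), and Id1 and Lefty1 without the filter (0.101 and 0.115).

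At the other stages 0 genes changed in Het or mHet (limma; at an unadjusted p under 0.05, 7 in oocytes, 72 at the 1-cell, 303 at the late 2-cell stage, 762 and 150 in the E3.5 tables and 650 in extraembryonic ectoderm). As values that did not pass, Plac8 stood at 0.75 ± 0.193 against 5.22 ± 1.2 FPKM in mHet and WT in the first E3.5 table and Mtfr1 at 5.65 ± 4.34 against 36.6 ± 1.18 in extraembryonic ectoderm (n = 2 each). The E3.5 counts became 1738 in the first table without WT replicate 2 and 1 without WT replicate 1, where Plac8 passed without WT replicate 2 (0.0285), and 1 in the second table without WT replicate 7. In extraembryonic ectoderm 2609 genes passed without mHet replicate 1, which left a mHet library with an Rn45s share of 11.6%, Mtfr1 among them (0.000972), and 1 gene passed without WT replicate 1. The median log2 change of all genes was 0.43 and 0.14 in the E3.5 tables and -0.20 in extraembryonic ectoderm. In the second E3.5 table X-linked genes were lower as a group in mHet too (camera, adjusted p = 1.46e-08; adjusted p = 0.954 with an estimated correlation), although with 139 genes higher and 149 lower and a median of -0.00848, against the median of 0.14 over all genes. The comparisons share the 5 WT libraries, and the X offset of mKO against mHet gave exact permutation p = 0.929. Of 756756 ways to group the 15 offsets, 0.722% put mKO as far below WT, and 1.1% of those mHet too. Splitting WT between the comparisons (lower in 20 of 20) decides nothing, as each WT offset exceeds both means.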

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

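Of the tests in this part, those of the Rn45s rescaling, the library run, the score difference between lists, the sex of the libraries, the Rn45s level and share and the WT libraries were chosen only after the result was seen, and the splits of the libraries before.

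Single libraries stood apart from their group in 6 of 73 groups of 4 or 5 values tested, where chance gives about 5%. In WT replicate 6 of the second E3.5 table, Fam122b was at 13.3 FPKM, against 5.13 to 6.6 in the other WT libraries. At E4.25, WT replicate 4 held Pramel6 at 28.8, Pramel7 at 12.2 and Slc15a2 at 7.18 FPKM, where the other WT libraries held at most 3.9, 1.82 and 1.27. In WT replicate 3 of that stage Wtap was at 1.41 FPKM, against 8.94 to 9.87, and Ccdc39 at 37 FPKM, against 0.424 to 4.35. Without the library that stood apart, each gene stayed past the threshold (limma), although Ccdc39 lost its call without other libraries, as given for that stage.

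For 7 gene lists the mKO effect differed between extraembryonic ectoderm and epiblast in the direct test (camera), which takes the tissues as independent; all 7 stayed past the threshold with embryos matched by sex. Relative to the other genes, the difference was negative for pluripotency genes of the inner cell mass (adjusted p = 0.000144), X-linked germline and placental clusters (0.00841), germline genes (0.0123) and mitotic cell cycle genes (0.0219). It was positive for visceral endoderm (5.2e-06), ribosomal protein (8.5e-06) and primitive endoderm genes (0.00932). With an estimated correlation 0 of these passed, the smallest adjusted p = 0.273 with an estimated correlation. Visceral endoderm lost its call without extraembryonic mKO replicate 2 (0.164), as did primitive endoderm (0.501), which was also lost without epiblast mKO column 4 (0.0978). Germline genes lost theirs without epiblast mKO column 4 (0.201) or extraembryonic mKO replicate 1 (0.0766), and the X-linked clusters without epiblast mKO column 3 (0.424). Cell cycle genes lost theirs without epiblast WT column 4 (0.0664), extraembryonic WT replicate 1 (0.0761), epiblast mKO column 3 (0.0866) or extraembryonic mKO replicate 1 (0.123).

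Many genes rose at E4.25. Of 35 splits of the 8 libraries only the real one gave 1394 genes (highest other 5) or 31 after median ratio scaling (highest other 1). This argues against chance for the count without excluding it, as 1 of 35 is the floor. For the number of lists called chance stays open, as 11 of the 35 splits called as many as the real 10, with up to 13. A term for the library run (1939 genes) decides nothing, because each run holds 2 WT and 2 mKO libraries, and 660 genes passed in the first run and 0 in the second (limma, 1536 at an unadjusted p under 0.05), although the median change was alike (0.74 and 0.76). The share of FPKM taken by Rn45s stays open as a cause, since 69 genes passed with Rn45s removed and the rest rescaled, which evens out any difference of totals, and 348 with its share alone divided out, but 1555 with its level as a term. Whether the 3 WT libraries set apart by their correlations carry the count is open too, as 0 genes passed without them (limma), with 1 WT library left and a median change of 0.82. An effect of genotype on early pluripotency genes relative to endoderm genes stays open: the score of totipotency minus that of visceral endoderm genes was 0.94 ± 0.41 in mKO and -0.97 ± 0.97 in WT (SD, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 can give). But WT replicates 1 to 3 lay at -1.67 to -1.02 and WT replicate 4 at 0.42, near the lowest mKO library (0.59), and both lists were picked from this comparison, so the reading was changed to open after the value was seen.

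X-linked genes were lower in mKO in the second E3.5 table (camera of limma, p = 6.12e-07; adjusted p = 0.957 with an estimated correlation), but 10 of 100 permutation splits of the WT and mKO libraries gave a p as small, down to 6.13e-09, so chance cannot be excluded for that list. It is argued against for the X-linked germline and placental clusters (2 of 100 splits, real p = 1.25e-07, smallest other 3.83e-08) and for X-linked genes in mHet (1 of 100, real 4.71e-10, smallest other 7.99e-10), but both share the WT libraries (mKO against mHet X offset, exact permutation p = 0.929). Sex stays open. The X offset of mKO minus WT was -0.15 in libraries without and -0.24 in those with Y-linked transcripts (stratified exact permutation p = 0.0167; mHet -0.13, p = 0.0667). But of the latter only WT replicate 7 had low Xist (3.72 against 28.6 to 168 FPKM), so they may mix sexes. The Rn45s level stays open: with it as a covariate the difference was -0.18 (mHet -0.17) as without it, but each exact permutation p = 0.0635. With chance open for the whole list, a lower output of X-linked genes in mKO embryos remains a hypothesis.

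The splits of the second E3.5 table also bear on its counts. As many as the real 5 changed genes in mKO came from 3 of 100 splits, which argues against chance by that measure without excluding it, but another split called 2203 genes. That split set WT replicates 3, 6 and 7 with mKO replicates 5 and 7 against the rest, that is, the 5 libraries with the lowest Rn45s share (9.19 to 31.5%) against those with 34 to 69.5%. For mKO against mHet a split by Rn45s share (9.19 to 21.1% against 34 to 69.5%) called 3592 genes where the real split called 1 (6 of 100 splits gave as many). Other splits that called 1715 (mKO against WT) and 2182 genes (mKO against mHet) followed the Rn45s share less closely, mHet replicate 3 (21.1%) standing with the higher and mKO replicate 6 (36.3%) with the lower shares in the second. These splits point to a structure of the samples other than genotype, of which the Rn45s share is 1 part. For the lists called, 6 of 100 splits gave as many as the real 9 in mKO against WT (highest other 11) and 6 as many as the real 8 in mKO against mHet (highest other 9). In mHet against WT 55 of 100 splits gave at least the real 3 lists (highest other 8). Chance can therefore not be excluded for these list counts or for the count of 1. With 0 genes in mHet the splits decide nothing, as all 100 must give as many (highest other 3). The splits covered counts and the X-linked lists and not each list called, and the oocyte and 8-cell comparisons, with 2 WT libraries, do not allow them.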

How the results depend on the processing

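Depth limits what these values can show, since the low FPKM carry no counts and most groups hold 2 libraries. Among the single genes followed through these settings, 1262 values under another setting and 995 with a library left out kept their direction and their side of the threshold. Another 201 and 127 no longer passed, 79 and 28 newly passed, and 8 and 21 reversed. For gene lists the numbers were 485 and 388 kept, 93 and 109 no longer past, and 4 and 8 reversed. Counts and levels stayed alike in 77 and 154, moved in 54 and 48 and no longer passed in 5 and 4. The number of list tests passing over the knockout comparisons, 59 as reported, ran from 44 to 57 under the planned settings that moved it and from 52 to 63 with a library left out, and totals keep the reported value for a stage at which a setting was not run. In what follows counts are of genes past the threshold, p-values of lists are adjusted, gene changes are on the log2 scale, and the cause was not tested unless stated. Wherever a count was 0 (limma), between 5 and 2388 genes had an unadjusted p under 0.05.

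Dropping the filter on low values, which adds genes to the adjustment, left 0 genes in mKO at the 1-cell, late 2-cell and 8-cell stages and in the first E3.5 table. It left 3 (all lower) in the second, 306 at E4.25, 17 in epiblast (6 higher, 11 lower), 1 in extraembryonic ectoderm, 15 in mHet epiblast (9 and 6), 3 in mHet extraembryonic ectoderm and 7 for the difference between the tissues (5 and 2). Ezhip then had a change of -3.74 (limma, adjusted p = 0.516) at the late 2-cell and -7.69 (0.0656) at the 1-cell stage. The X offset difference of the second E3.5 table became -0.00388 in mKO and -0.0348 in mHet, and its X-linked clusters had a p of 0.46. A pseudocount of 0.1 left 0 genes in mKO at the late 2-cell and 8-cell stages and in mKO and mHet epiblast, with 868 at E4.25 and 8, all lower, in extraembryonic ectoderm. It gave 1 for the difference between the tissues and 7 for knockout against heterozygous, and Ezhip at the late 2-cell stage had a change of -5.93 (0.252).

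Median ratio scaling left 0 genes in mKO at the 8-cell stage and in mKO and mHet epiblast. It gave 11 in the second E3.5 table (1 higher, 10 lower), 1 there in mHet, 31 at E4.25 (30 and 1), 4, all lower, in extraembryonic ectoderm and 29 for knockout against heterozygous. Of the 11 genes then called in the second E3.5 table and tested in the first, 11 had the same sign there. The visceral endoderm list at E4.25 had a p of 0.0884, Phf17 in the first E3.5 table reversed to -0.0821 and Sfmbt2 in extraembryonic ectoderm to 0.19. With the 2 groups alone, which leaves fewer libraries to estimate spread, the first E3.5 table gave 1 gene, the second 8, mKO and mHet epiblast 0 and knockout against heterozygous 32.

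Settings chosen after seeing the data moved these values. With a sex term the 8-cell stage gave 0 genes, the second E3.5 table gave 3, E4.25 gave 2121 and epiblast 0. With the library run as a term the 8-cell stage gave 4 (1 and 3) and the oocyte-specific list in oocytes reversed (0.568). The first run alone gave 660 genes at E4.25 (601 and 59) and the second run alone 0 (limma), where the visceral endoderm list had a p of 0.27. Removing Rn45s gave 12 genes in the first E3.5 table (4 and 8) and 69 at E4.25 (66 and 3), with a p of 0.0704 for visceral endoderm there, and reversed Phf17 (-0.26) and Smoc1 (-0.0368) in the first E3.5 table and Sfmbt2 (0.0365) in the second. The Rn45s level as a term gave 59 genes in the first E3.5 table (33 and 26) and 22 in the second (9 and 13), with Phf17 at -0.32 in the first and Sfmbt2 at 0.0964 in the second, and 1555 at E4.25 (1464 and 91). Dividing out the Rn45s share alone gave 348 at E4.25 (339 and 9). WT replicate 4 as the only WT library there gave 0 genes (limma), reversed Gadd45a (0.21) and the lists of glycolysis (0.751), oxidative phosphorylation and primitive endoderm (0.88 each), and ended visceral endoderm (0.683).

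With the replicate number as a replicate block, 123 genes passed at the 8-cell stage (29 and 94; Snx10 at 1.11e-05, Serping1 at 0.00027, Oosp1 at 0.00408 and Fgf4 at 0.00433), 13 in the first E3.5 table (7 and 6), 11 in the second (2 and 9; Plod2 at 0.00952 and Xlr3b and Xlr4b at 0.0263) and 1 there in mHet. In oocytes 2 passed in KO (1 and 1) and 1 in Het, at the late 2-cell stage 22 (16 and 6), and for knockout against heterozygous 111. Same-numbered mKO and WT libraries deviated with correlations across genes of -0.20, 0.48, -0.41, 0.15 and 0.70 in the second E3.5 table and 0.0586, 0.0875, 0.14 and 0.10 at E4.25, so the numbers do not pair the samples, and with fewer than 3 pairs elsewhere this was left undecided. At E6.5 the block only set apart extraembryonic libraries of replicate 2, and epiblast columns, lacking title numbers, allowed no pairing. Y-linked transcripts stood at 34.6 to 90.7 FPKM in WT column 3 and replicate 1 and in mKO column 4 and replicate 2, and at most at 0.19 in the other WT and mKO libraries, which hints that columns 3 and 4 match replicates 1 and 2. With this matching, chosen after seeing the data, the difference between tissues kept 0 genes (limma) and all its 7 lists (visceral endoderm 1.35e-08).

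Leaving out each library in turn moved the mKO or KO counts to between 1 and 6 in oocytes, 0 at the late 2-cell stage under each, 0 to 3 at the 8-cell stage, 2 to 52 in the first and 3 to 12 in the second E3.5 table, 297 to 1909 at E4.25, 0 in epiblast under each and 0 to 9 in extraembryonic ectoderm. Heterozygous counts ran from 0 to 1 in oocytes, 1-cell and late 2-cell embryos and the second E3.5 table, 0 to 1738 in the first E3.5 table, 0 to 2 in epiblast and 0 to 2609 in extraembryonic ectoderm. The difference between the tissues ran from 0 to 5 genes and knockout against heterozygous from 8 to 418. Ezhip at the late 2-cell stage ran from -4.07 to -3.41.

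Of the list p-values with a library left out, the imprinted core in epiblast ran from 1.63e-05 to 0.422, X-linked genes at the 8-cell stage from 2.64e-16 to 0.0671, oocyte-specific genes in oocytes from 7.45e-26 to 0.797, visceral endoderm in extraembryonic ectoderm from 7.53e-27 to 0.124 and between the tissues from 5.62e-22 to 0.164. Oxidative phosphorylation genes ran from 1.07e-12 to 0.0925 in the first E3.5 table and from 3.95e-10 to 0.985 in late 2-cell mHet, where they reversed. Genes of the p53 and integrated stress responses at the 8-cell stage ran from 2.54e-05 to 0.881, primitive streak genes in epiblast from 1.2e-06 to 0.422 and ribosomal protein genes in Het oocytes from 1.33e-15 to 0.00855, each with a reversal.

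Single genes that did not pass reversed with a library left out. In oocytes Cyp11a1 ran from -2.38 to 0.35 and Oog1 from -0.0777 to 0.86. In the first E3.5 table Phf17 ran from -0.52 to 0.82 and Sfmbt2 from -1.11 to 0.14, and in the second Sfmbt2 from -0.60 to 0.22 and Xist from -0.37 to 0.97. In epiblast Elf5 ran from -0.0167 to 4.18, Phf17 from -0.0552 to 1.48 and Xist from -2.17 to 1.598. In extraembryonic ectoderm Ccnd2 ran from -1.65 to 0.00938, Sfmbt2 from -0.31 to 0.17, Slc38a4 from -0.12 to 0.48 and Xist from -0.93 to 1.87. The test of E4.25 mHet against WT was not run, because the identical libraries left 1 sample.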

Other observations

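Of the tests in this part, the spread of Casc4 within a genotype and the alternatives for knockout against heterozygous were chosen after the result was seen, while the Casc4 neighbours were chosen before, and their SD and lengths after.

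Knockout set directly against heterozygous libraries showed a few further genes, all chosen after their values were seen apart from those of the lists. At the late 2-cell stage 6 genes were higher and 3 lower in mKO than in mHet (limma; 16 and 3 with median ratio scaling). Of the 2-cell-stage genes, BC080695 was at 61.1 ± 7.29 against 13.1 ± 1.93 FPKM in mKO and mHet (SD, n = 2 each), Gm4340 at 63 ± 26.5 against 4.5 ± 2.31 and Gm5662 at 105 ± 7.64 against 20.3 ± 7.24. Each had an adjusted p = 0.0477, and reads may be shared among near-identical copies of these genes. Mtx2 was at 4.3 ± 0.593 against 20.8 ± 3.79 FPKM (adjusted p = 0.0477). These 4 calls ended with a pseudocount of 0.1 (0.0578), without the filter (0.385 to 0.402), with the 2 groups alone (0.0597 to 0.0665), and without mHet replicate 1 (0.138), mKO replicate 1 (0.126 to 0.156) or mKO replicate 2 (0.245). Without any 1 of these 3 libraries 0 genes passed (limma; 906, 805 and 1088 at an unadjusted p under 0.05). The Mtx2 call also ended without mHet replicate 2 (0.082), where 25 passed.

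Later stages gave fewer such genes. In the second E3.5 table Msn was lower in mKO than in mHet, at 1.47 ± 0.602 against 9.06 ± 3.31 FPKM (SD, n = 5 each; -1.99, limma adjusted p = 0.0283), with 0 higher and 1 lower, or 1 and 3 with median ratio scaling, which moved the median change from -0.24 to -0.0388. Msn lost this call without mHet replicate 4 (0.13), 5 (0.144) or 6 (0.13) and without mKO replicate 3 (0.107), 4 (0.0987) or 6 (0.15), as well as without the filter (0.0818) and with the 2 groups alone (0.0802). The count was 3 genes without mKO replicate 7 and 2 without mHet replicate 3. In the first E3.5 table, there were 2 genes higher and 2 lower (13 and 17 with the 2 groups alone, 1 and 2 with median ratio scaling, which moved the median change from -0.23 to 0.0243), and sex differed with genotype as it did against WT. Thcytx was at 5.58 ± 0.352 against 0.176 ± 0.0132 FPKM, Tsix at 79.4 ± 27.5 against 1.34 ± 0.472, and the Y-linked genes Eif2s3y at 0.0729 ± 0.00184 against 44.4 ± 22.7 and Ddx3y at 0.0399 ± 0.0565 against 15.4 ± 5.73 (n = 2 each). Tsix lost its call without mHet replicate 1 (0.184) or 2 (0.463), and Eif2s3y without mHet replicate 2 (0.21), mKO replicate 1 (0.0569) or mKO replicate 2 (0.0979). Ddx3y lost its call without mHet replicate 2 (0.21) or mKO replicate 2 (0.0979), and Thcytx without mHet replicate 1 (0.33), mHet replicate 2 (0.586), mKO replicate 1 (0.0845) or mKO replicate 2 (0.161) and with a pseudocount of 0.1 (0.0771) or median ratio scaling (0.123). All 4 calls ended without the filter (0.259 to 0.295). The count of 4 fell to 2 without mHet replicate 1, 0 without mHet replicate 2 (limma; 233 at an unadjusted p under 0.05) and 2 without mKO replicate 2. In extraembryonic ectoderm Ccl20 was listed at 0 in both mKO libraries and at 8.35 ± 4.6 FPKM in mHet (limma, adjusted p = 0.00479; 1 with the 2 groups alone), where 402 genes passed without mHet replicate 1, 12 without mKO replicate 1 and 3 without mKO replicate 2. In epiblast 0 genes passed (limma; 271 at an unadjusted p under 0.05) and 1 did without mHet column 4. In oocytes and 1-cell embryos Ezhip was the only gene to pass, with 2 genes without Het replicate 1, 3 without KO replicate 3 and 2 without 1-cell mHet replicate 2.

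Genes of the germline, a class silenced in somatic cells, were higher as a group in mKO epiblast than in WT (camera, adjusted p = 0.000475; adjusted p = 0.509 with an estimated correlation; 16 of 18 higher, 0 adjusted over the list alone), with Tuba3a, a tubulin of testis, at 7.92 ± 4.58 against 2.12 ± 1.7 FPKM, not past the threshold. This call ended without mKO column 4 (0.172). Against mHet they were higher too (camera, adjusted p = 3.02e-09; adjusted p = 0.474 with an estimated correlation; 15 of 18 higher, 4 adjusted over the list alone), under every alternative run. The 6 core genes imprinted through H3K27me3 were higher as a group in mKO than in mHet in epiblast (camera, adjusted p = 0.000205; adjusted p = 0.474 with an estimated correlation) and in extraembryonic ectoderm (camera, adjusted p = 0.00453; adjusted p = 0.907 with an estimated correlation; in both 5 of 6 higher, and 0 and 1 adjusted over the list alone). The epiblast call ended without mKO column 3 (0.455) and the extraembryonic one without mHet replicate 1 (0.164) or mKO replicate 1 (0.132).

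Casc4 fell in mKO at the 8-cell stage and in epiblast and in mHet epiblast. A level that differs between libraries of 1 genotype is a candidate. In FPKM, mHet ran from 0.967 to 7.33 (ratio 7.57) in the second E3.5 table and mKO from 1.76 to 7.74 at E4.25, and WT of the first E3.5 table was at 2.78 and 20.6. But mKO there was at 0.711 and 0.772, below mHet too (4.64 and 10.1), where sex differed and 45.4% of genes kept these groups apart. The second table averaged 0.965 in mKO and 1.57 in WT. At E4.25 mKO was higher, at 3.45 ± 2.88 against 0.886 ± 0.321 (SD, n = 4 each, no overlap; limma adjusted p = 0.089). Reads assigned to a neighbouring gene stay open. The neighbour Ctdspl2 gained 29.4% of the FPKM that Casc4 lost at the 8-cell stage and 2.46% in epiblast. With the SD of both groups added and FPKM multiplied by gene length, this could be 136% and 52.6%, over the bound of 50% set before. An effect of genotype on Casc4 also stays open.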
